A study of Mus musculus with 6 samples.

How the data were processed

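Brain cells of C57BL/6 mice aged 6 to 8 weeks were profiled 24 h after middle cerebral artery occlusion (MCAO, an experimental ischemic stroke) or sham surgery, with 3 droplet libraries per group and 6 in all. Per the labels' protocols, tissue was digested with papain for 30 min at 37 °C, passed through a 40 µm strainer, freed of myelin on 30% Percoll and stained for viability before 3' single-cell libraries were made with the Chromium kit. The labels do not say whether each library came from one animal, which part of the brain was taken, or on which day and at what time of day it was collected.

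Per the labels, Cell Ranger and STAR were run with the mm10 genome build. Their versions, the gene annotation and the setting used to call cells are not given in the sources used here. The deposited files hold raw UMI counts per gene and cell barcode, one matrix per library, with barcodes already restricted to called cells. UMI counting is inferred from the kit and from Cell Ranger in the labels. The gene table is the same in the 6 libraries and lists 27998 genes by Ensembl ID and symbol, and 56 symbols are used by more than 1 gene. Gene coordinates in the text come from a GENCODE vM21 copy on mm10, whose release may differ from the one used for counting, and 340 of the 341 genes selected for naming had a position.

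The sham libraries held 8771, 8540 and 9980 barcodes with 25377653, 25135690 and 29771389 UMIs. The MCAO libraries held 11772, 11361 and 8104 barcodes with 42848023, 40306707 and 34617621 UMIs. Median UMIs per barcode were 2391, 2422 and 2471 in sham and 2982, 2883 and 3495 in MCAO. Barcodes with fewer than 300 detected genes (15) or more than 10% mitochondrial UMIs (1298) were removed. Doublets (4454) were then removed by comparing each barcode with simulated pairs, after the idea of Scrublet with code of its own, at a rate of 0.8% per 1000 barcodes, which took 6.34% to 9.18% per library. This left 52761 of 58528 barcodes: 7995, 7794 and 9015 sham cells and 10413, 10116 and 7428 MCAO cells.

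Cells of all libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were kept, and a shared-neighbour graph with 20 neighbours was partitioned by the Leiden method at resolution 1.0 and seed 1. Each of the 30 clusters was named by its markers, taken from lists for each cell type fixed before the data were examined. A name needed at least 3 markers detected in 25% of the cells. A rule that leaves a cluster unnamed when it detects markers of a second class (second score at least 0.28 and at least 0.4 of the first, with at least 5 of its markers) was set after the clusters were seen. It left 2 clusters unnamed, with 0.392% ± 0.229 (SD, n = 3) of sham and 0.147% ± 0.0316 of MCAO cells. Another cluster had under 3 markers detected, with 0.868% ± 0.113 and 2.11% ± 0.162. Class names stand for "-like" cells throughout, since they rest on RNA markers alone.

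For each class with at least 20 cells in every library, raw counts were summed per library and compared between groups with edgeR's quasi-likelihood test (filterByExpr, TMM scaling, robust fit), with group as the only term. Adjusted p-values are Benjamini-Hochberg values over the genes tested in the class, with a threshold of 0.05. Expression is given in CPM (counts scaled to 1e+06 per profile) with TMM scaling, as mean and SD over the 3 libraries of a group, and changes are MCAO over sham on the log2 scale with their SE, the size of the change over the root of the F statistic (none is given where F is under 1e-04). Cell numbers per class were compared with the same test, with the log of the kept cells as offset, beside an exact two-sided permutation test of the shares. Fixed gene lists (16 shared by all classes and others for single classes, 33 in all) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a class, and again with a correlation estimated per list and with fry. Differences of the change between classes were tested as interactions in one edgeR fit over both classes, with library as a term. A fold against a group without any UMI of the gene was computed against a floor of 3 counts over the group and is a lower bound. The classes of interest, lists, markers, tests and alternatives were chosen before the data were examined, except where the text says otherwise.

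Genes to be named were picked by a rule fixed in advance. In the 3 main classes (microglia, endothelial cells and astrocytes) it took the 12 highest and 8 lowest log2 fold changes among genes past the threshold, with a mean of at least 50 CPM and groups that did not overlap, which chance gives for 10% of genes. Their CPM had to reach 10% of that in the class with the highest level (in the MCAO group for higher and the sham group for lower genes), and markers of other classes, mitochondrial, ribosomal protein, hemoglobin and provisional genes were left out. Up to 4 members per list with the smallest adjusted p were added. Other classes took the 3 highest and 3 lowest by the same rule. Each difference between classes took the 5 largest in each direction among genes past the threshold with a mean of at least 50 CPM in either class. The same kinds of genes were left out there, so larger differences of genes with lower expression are not named. A few genes that the rule or the lists hold are not reported here. Other list members, markers and clock genes that the text names were chosen after their values were seen: Ankrd37, Bnip3, Cd44, Cxcl10, Cxcl12, Dbp, Ddit4, Fabp5, Fcrls, Gpnmb, Hk2, Igf1, Il6 and Trem2 in microglia, Abcb1a, Apcdd1, Arntl, Cdh5, Cldn5, Cxcl10, Icam1, Ifi204 and Slc2a1 in endothelial cells, and Osmr in astrocytes. The members set against microglia markers were taken as a set, by their highest class.

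On counts simulated from the real means, library sizes and dispersions, with 200 changed genes, the test recovered 82.1% of genes changed 2-fold in microglia (11515 genes tested), 88.1% in endothelial cells (12403) and 71.6% in astrocytes (10137), and 65.7%, 74.6% and 25.4% of those changed 1.5-fold. Among the calls, 7.4%, 9.3% and 8.5% were unchanged genes. In monocyte-derived cells 38.8% of genes changed 2-fold were recovered and 14.2% of calls were unchanged genes, and in fibroblasts 44.8% and 13.8%, so smaller changes in these classes would often be missed. The interaction test made 12.4%, 6.4% and 6.8% false calls in the pairs of microglia and endothelial cells, microglia and astrocytes, and endothelial cells and astrocytes.

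Alternatives covered DESeq2's size factors and its Wald test, limma-voom, no filter on low counts, a 2-fold minimum, each library left out in turn, the replicate number as a block, mitochondrial limits of 5% and 20%, doublets kept, resolutions 0.5 and 2.0, profiles thinned to the smallest total, and genes left out whose CPM was under 10% of that in the class with the highest CPM, as possible free RNA. Cell numbers were also compared among cells outside the leukocyte classes other than microglia and with TMM over classes, and the differences between classes without the library term. Splits of mixed clusters, unnamed clusters added to their nearest class, and clusters with a marker score under 0.5 left out were added after seeing the data. The listed genes missing from the table (Trbc2, Ighm, Igkc, Clec7a and Itgam) were not analysed here. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.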

Results

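The data are single-cell RNA counts from mouse brain 24 h after MCAO or sham surgery, in 6 droplet libraries, 3 per group. The sham libraries held 8771, 8540 and 9980 barcodes and the MCAO libraries 11772, 11361 and 8104, with 25135690 to 42848023 UMIs per library. After filters 52761 cells remained. The median kept cell had 2328, 2361.5 and 2402 UMIs in the sham and 2858, 2761.5 and 3407.5 in the MCAO libraries. Counts per cell also depend on the RNA and the mix of cells. The endothelial cluster with most sham cells had a median of 2063.5 UMIs, and the main MCAO ones 2090 and 3043. The microglia cluster with most sham cells had 2402.5, and the main MCAO ones 3009.5, 5037.5 and 2593. Clusters were named by fixed marker genes, and every class name below stands for cells like that type. Expression is in CPM of the class's summed profile, as mean ± SD over the 3 libraries of a group, and a change is the log2 of MCAO over sham ± SE with n = 3 libraries per group. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from limma's camera. They measure only the spread between these libraries, which can be technical, since the labels do not say that each library is a separate animal.

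The first comparison asks which cell types made up the captured cells in each group. Monocyte-derived cells, which enter the brain from blood, rose from 0.561% ± 0.0361 of kept cells in sham to 5.11% ± 0.149 in MCAO (SD, n = 3), a log2 change of 3.18 ± 0.09. The cluster with most sham cells of this class held 137 sham and 304 MCAO cells, and another held 2 and 1119. The rise is thus mostly that of a cluster nearly absent from sham. Neutrophils rose from 0.488% ± 0.0125 to 1.64% ± 0.182, and T or NK lymphocytes from 0.516% ± 0.0468 to 1.04% ± 0.0641. The single cluster of that class, with 8 of its markers detected, also had a B cell score of 0.848 beside its own score of 1, with 0 B cell markers detected in 25% of its cells, so any B cells in it were not set apart. Among resident cells, pericytes, which wrap capillaries, rose from 0.738% ± 0.0854 to 2.26% ± 0.0489 and astrocytes from 3.75% ± 0.178 to 6.78% ± 0.294. Endothelial cells fell from 54.1% ± 0.524 to 41.4% ± 1.08 and microglia from 23.9% ± 0.755 to 21.4% ± 0.297. The microglia share includes 2 clusters with low marker scores (0.394 and 0.358), with 2403 and 504 MCAO cells against 21 and 2 sham cells. Whether these cells are microglia or macrophages from blood was not tested, and shares without them were not computed. Leaving them out would lower the MCAO share of microglia far more than the sham share.

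Smaller changes of share were a log2 change of 0.62 ± 0.07 in oligodendrocytes, 0.55 ± 0.05 in choroid plexus epithelium and 0.14 ± 0.05 in smooth muscle. Neuroblasts rose by 1.17 ± 0.29 and erythrocytes by 2.63 ± 0.44, the latter on 6 sham and 44 MCAO cells. Altogether 12 of 15 classes changed in edgeR's test, with adjusted p-values from 8.99e-42 in monocyte-derived cells to 0.0215 in smooth muscle. Border macrophages (0.03 ± 0.06, adjusted p = 0.749), fibroblasts (0.00, 0.978) and ependymal cells (-1.53 ± 0.77, 0.137) did not pass. The exact two-sided permutation test of the shares gave 0.1 for each class that changed, the smallest value that 3 against 3 libraries allow. These are shares of cells captured after digestion and Percoll, not densities in tissue, and with TMM over classes smooth muscle (-0.35), border macrophages (-0.46) and fibroblasts (-0.48) turned to lower shares past the threshold. Under that setting the changes of oligodendrocytes and choroid plexus epithelium no longer passed, and that of ependymal cells did. Unnamed clusters held 1.26% ± 0.201 of sham and 2.25% ± 0.156 of MCAO cells.

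**Figure D1:**
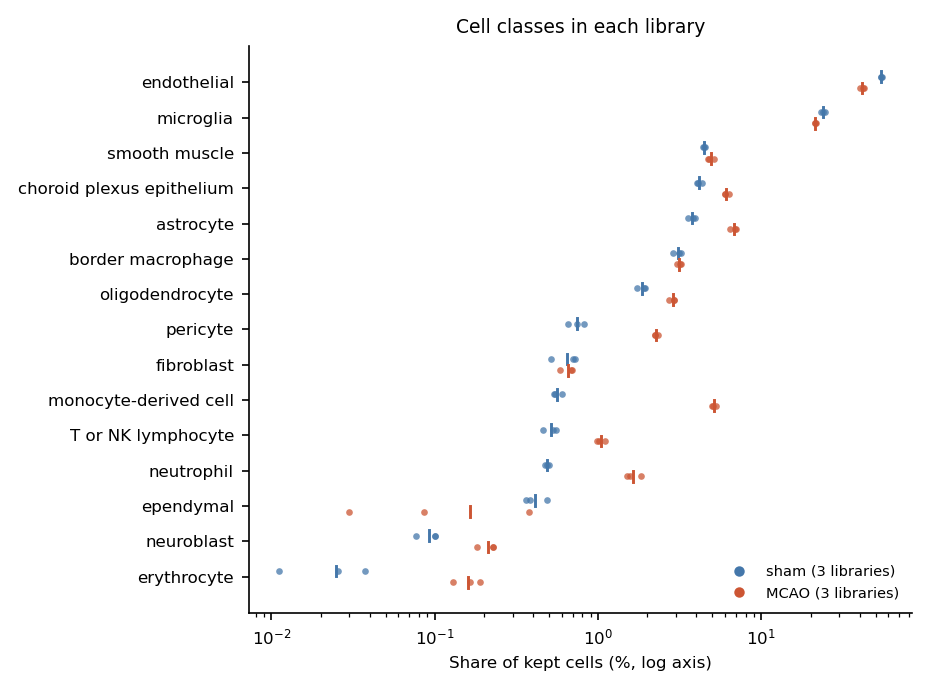
Share of kept cells in each class (percent, log axis), with a dot per library and a tick at the group mean, for 3 sham and 3 MCAO libraries. Monocyte-derived cells lie at a mean of 0.561% in sham and 5.11% in MCAO, and endothelial cells at 54.1% and 41.4%.

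The next comparison asks how microglia, the resident macrophages of the brain, differ in expression after MCAO. Spp1, which encodes the secreted protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 18.6 ± 6.87 to 18870 ± 663 CPM (SD, n = 3). P2ry12, which encodes a purinergic receptor of surveying microglia (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), fell from 3874 ± 155 to 456 ± 10.3 CPM. Among the genes with the highest changes, the lipoprotein lipase gene Lpl rose by 5.43 ± 0.07, the scavenger receptor gene Msr1 by 7.05 ± 0.09, Lgals3 by 6.02 ± 0.16 and the elastase gene Mmp12 by 9.29 ± 0.17. The sham microglia lay almost wholly in 1 cluster (96.4% of them, against 1.59% of MCAO microglia), and MCAO microglia in other clusters that held 49.7%, 40.2% and 8.44% of them. The sham cluster had a microglia marker score of 0.998, and these 3 had scores of 0.69, 0.394 and 0.358. The clusters at 0.394 and 0.358 held 2403 and 504 MCAO cells against 21 and 2 sham cells. Whether these are changed resident microglia or macrophages from blood was not tested. Without them, an alternative chosen after seeing the data, 137 named-gene results kept direction and side of the threshold, 4 were weaker, 1 stronger and 1 reversed.

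Of the homeostatic microglia list, 15 of 16 members fell and 1 rose (median -1.78, adjusted p = 6.9e-08; adjusted p = 0.287 with an estimated correlation). Siglech fell from 1095 ± 90.0 to 190 ± 12.1 CPM, Gpr34 by 2.19 ± 0.05 and the fructose transporter gene Slc2a5 by 2.67 ± 0.06, while Fcrls rose by 0.33. P2ry12, Siglech, Gpr34, Tmem119, Cx3cr1, Sall1, Olfml3, Fcrls and P2ry13 of this list also served to name the class. The counts adjusted over the list alone equalled those over all genes for the microglia lists given here.

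The disease-associated microglia list, drawn from neurodegeneration, had 16 members higher, 1 lower and 3 that did not pass (median 1.84, adjusted p = 1.39e-06; adjusted p = 0.105 with an estimated correlation). Besides Spp1 and Lpl, Gpnmb rose by 4.69, Igf1 by 3.27, Fabp5 by 3.15 and the lysosomal membrane gene Cd63 by 2.44 ± 0.05, while the receptor gene Trem2 fell by 1.01. Lipid storage and efflux genes had 9 members higher and 2 lower of 12 (median 1.54, adjusted p = 0.00286; adjusted p = 0.145 with an estimated correlation). The lipid droplet gene Plin2 rose from 44.6 to 588 CPM and Lpcat2 fell by 1.34 ± 0.05.

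Cytokines and chemokines had 16 of 18 members higher and 2 lower (median 3.22, adjusted p = 8.31e-08; adjusted p = 0.105 with an estimated correlation). The monocyte chemokine gene Ccl12 rose from 540 ± 45.3 to 6481 ± 270 CPM, Ccl3 from 602 ± 35.3 to 3533 ± 115 CPM and the cytokine gene Osm by 3.23 ± 0.08, while Cxcl12 fell by 1.44 and Il6 by 0.50. Il1rn rose by 9.52 ± 0.16 and stood at 28.3% of its neutrophil CPM. The complement genes went both ways (4 higher, 4 lower, median 0.22, adjusted p = 0.605), with the anaphylatoxin receptor gene C5ar1 higher by 3.08 ± 0.06 and C1qc lower by 0.45 ± 0.05. Interferon response genes also went both ways (10 higher, 5 lower of 20, adjusted p = 0.227), with Cxcl10 at 4.03 and Rtp4 at -0.94 ± 0.05.

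Stress and metabolic lists rose. Hypoxia and glycolysis had 17 members higher and 4 lower of 23 (median 0.88, adjusted p = 0.000188; adjusted p = 0.105 with an estimated correlation). Its pyruvate kinase gene Pkm rose from 258 ± 5.75 to 1382 ± 54.8 CPM, while the hypoxia-induced genes Bnip3, Ddit4, Ankrd37 and Hk2 fell. ER stress genes had 16 of 17 members higher (median 1.08, adjusted p = 9.3e-07; adjusted p = 0.156 with an estimated correlation), among them the chaperone gene Hspa5 at 1.81 ± 0.05. NRF2 targets, metallothioneins and ferritin had 12 of 16 higher (median 1.70, adjusted p = 1.06e-05; adjusted p = 0.119 with an estimated correlation), with the heme oxygenase gene Hmox1 at 64.3 ± 0.922 and 380 ± 13.6 CPM. Cell cycle genes had 16 of 21 higher (median 1.33, adjusted p = 1.16e-05; adjusted p = 0.156 with an estimated correlation), with the replication gene Mcm2 at 3.08 ± 0.18. Cdkn1a, which halts the cycle, also rose, by 3.23 ± 0.06.

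Among the other lists, ribosomal protein genes had 26 of 26 higher (median 0.74, adjusted p = 3.4e-09; adjusted p = 0.457 with an estimated correlation) and oxidative phosphorylation 27 of 29 (0.44, 3.91e-07; adjusted p = 0.199 with an estimated correlation). Heat shock genes had 14 of 15 higher (0.75, 4.24e-05; adjusted p = 0.161 with an estimated correlation) and extracellular matrix genes 13 of 16 (1.80, 7.95e-05; adjusted p = 0.105 with an estimated correlation), among them Cd44 at 4.32 and Itga5 at 3.67 ± 0.12. Genes of p53 targets and cell death had 11 of 17 higher and 3 lower (0.95, 0.00533; adjusted p = 0.145 with an estimated correlation), NF-kB genes 9 of 16 higher and 2 lower (0.52, 0.0191; adjusted p = 0.304 with an estimated correlation), and cholesterol synthesis 8 of 18 higher (0.41, 0.0183; adjusted p = 0.463 with an estimated correlation). Lysosome and phagocytosis (9 higher, 7 lower, adjusted p = 0.593), MHC class I (2 higher, 9 lower, 0.0728), MHC class II (4 higher, 2 lower, 0.652) and immediate early genes (9 higher, 5 lower, 0.255) had no call.

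Across all 11709 genes tested in microglia, 3507 were higher and 3727 lower in MCAO, and 1058 and 1070 of them by at least 2-fold. Of the 21 lists, 14 were higher and 1 lower, and 0 of them passed with an estimated correlation, where the lowest adjusted p was 0.105. The estimated correlation was 0.01 for the cytokine and disease-associated lists, equal to the preset one, and 0.83 for ribosomal protein genes. Correlated members therefore cannot account for every lost call, and a lost call does not by itself show correlated members. With fry the adjusted p was 8.38e-07 for the cytokine list, 8.38e-07 for the disease-associated list and 0.000161 for ribosomal protein genes. Summed profiles held 4477905 to 8936582 UMIs. Marker lists of other cells moved too: monocyte-derived cell markers had a median of 1.01 (adjusted p = 0.00936; adjusted p = 0.353 with an estimated correlation) and endothelial markers of -0.46 (0.0439; adjusted p = 0.659 with an estimated correlation). Astrocyte markers had 10 of 12 higher (1.11, 0.015; adjusted p = 0.595 with an estimated correlation), pericyte markers 8 of 9 (0.72, 0.0209; adjusted p = 0.595 with an estimated correlation) and erythrocyte markers 4 of 4 (4.22, 0.0271; adjusted p = 0.513 with an estimated correlation). Of the genes that rose, 513 (14.6%) had under 10% of the CPM of the class with the highest level. Over all genes tested in microglia this share was 16.9%. The clock output gene Dbp fell by 3.48 ± 0.10 in microglia and fell in each of the 10 classes where it was tested.

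Endothelial cells were compared to ask how the brain's vessel lining changed. Ackr1, a chemokine-binding receptor gene of venules (ENSMUSG00000037872, chromosome 1, 173331886 to 173333750), rose from 52.1 ± 17.5 to 469 ± 34.7 CPM (SD, n = 3), and Lrg1 from 124 ± 10.6 to 837 ± 10.5 CPM. Angpt2, which loosens vessels, rose by 2.53 ± 0.07 and the metallothionein gene Mt2 by 2.77 ± 0.05. Ifit3, an interferon-induced gene (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), fell from 520 ± 24.2 to 194 ± 11.4 CPM, and Cxcl12 from 1376 ± 109 to 482 ± 15.6 CPM. Of sham endothelial cells 75.5% lay in a cluster that held 4.51% of the MCAO ones, of which 50.7% and 28.8% lay in other clusters.

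Interferon response genes fell, with 17 of 20 members lower and 2 higher (median -0.69, adjusted p = 2.19e-06; adjusted p = 0.0524 with an estimated correlation), and 17 lower and 3 higher adjusted over the list alone. Ifit1 fell by 1.33 ± 0.05 and the regulator gene Irf7 by 1.09 ± 0.04, while Cxcl10 rose by 2.37 and Ifi204 by 1.42. MHC class I presentation had 10 lower and 2 higher of 15 (median -0.20, adjusted p = 0.0109; adjusted p = 0.174 with an estimated correlation), with the immunoproteasome gene Psmb9 at -0.92 ± 0.05. Genes of the Wnt and beta-catenin pathway, which maintains barrier properties, had 13 of 16 lower and 0 higher (median -0.47, adjusted p = 2.37e-05; adjusted p = 0.0524 with an estimated correlation), with Apcdd1 at -2.01 and Notum at -1.25 ± 0.06.

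Tight junction and transporter genes had 12 of 19 lower and 4 higher (median -0.41, adjusted p = 0.0018; adjusted p = 0.388 with an estimated correlation), and 13 lower adjusted over the list alone. Spock2 fell from 1468 ± 45.1 to 538 ± 31.0 CPM, the organic anion transporter gene Slc22a8 by 0.78 ± 0.04 and the junction gene Tjp1 by 0.73 ± 0.04. Abcb1a fell by 0.93 and the glucose transporter gene Slc2a1 rose by 0.35, both of which are also naming markers, like Slco1a4 and Kdr. Cldn5 (-0.04) and Cdh5 (0.01), which also served to name the class, did not pass. Leukocyte adhesion genes had 8 of 13 higher and 1 lower (median 0.28, adjusted p = 0.00233; adjusted p = 0.127 with an estimated correlation), and 9 higher adjusted over the list alone. Selp, which tethers leukocytes, rose from 0.958 ± 0.645 to 17.0 ± 2.44 CPM, Sele by 3.42 ± 0.33 and Icam1 by 1.04.

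Coagulation and fibrinolysis had 9 of 11 members higher and 0 lower (median 0.75, adjusted p = 5.21e-05; adjusted p = 0.127 with an estimated correlation). The plasminogen activator gene Plat rose from 318 ± 10.8 to 1058 ± 57.9 CPM. Extracellular matrix genes had 14 of 18 higher (median 1.37, adjusted p = 3.87e-06; adjusted p = 0.0524 with an estimated correlation), with the collagen gene Col4a1 at 1.25 ± 0.04. Heat shock genes had 12 of 15 higher, 13 adjusted over the list alone (median 0.59, adjusted p = 3.87e-06; adjusted p = 0.0524 with an estimated correlation). Tip cell and angiogenesis genes went both ways (8 higher, 8 lower, adjusted p = 0.793), with Apln at 2.84 ± 0.13 and the VEGF receptor gene Kdr at -0.63 ± 0.05.

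Cytokines and chemokines had 17 of 19 members higher in endothelial cells (median 2.90, adjusted p = 1.57e-07; adjusted p = 0.217 with an estimated correlation), and 18 adjusted over the list alone. For 8 of them (Il1a, Csf1, Cxcl10, Cxcl16, Ccl12, Ccl3, Ccl4 and Tnf) microglia had the highest level in MCAO, and endothelial cells stood at a median over the genes of 4.13% to 5.76% of it in the MCAO libraries, where microglia markers stood at 4.52% to 5.84%. Csf1 was apart from the others, at 24.6% to 28.6% in MCAO and 159% to 222% in sham. Cxcl10 and Cxcl16 also stood above the markers, at 9.51% to 12.4% and 8.41% to 9.36% in MCAO. Without members under 10% of the highest class, the list's median was 0.28 and its call was lost. Markers of astrocytes (median 1.02, adjusted p = 2.37e-05; adjusted p = 0.247 with an estimated correlation) and erythrocytes (4.34, 0.000156; adjusted p = 0.217 with an estimated correlation) were also higher. So were those of monocyte-derived cells, with 8 of 9 higher (1.29, 0.00233; adjusted p = 0.174 with an estimated correlation), pericytes, with 8 of 9, or 9 adjusted over the list alone (0.73, 0.0013; adjusted p = 0.254 with an estimated correlation), and oligodendrocytes, with 5 of 10 (0.53, 0.0266; adjusted p = 0.623 with an estimated correlation).

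Other lists that rose were ER stress, with 14 of 18 higher (median 0.78, adjusted p = 1.04e-05), NRF2 targets with 13 of 16 (0.57, 4.12e-05), hypoxia and glycolysis with 17 of 23 (0.35, 2.23e-05), NF-kB with 13 of 16 (0.70, 0.000324), immediate early genes with 12 of 18 (0.29, 0.000353) and p53 targets and cell death with 13 of 17 (0.54, 6.08e-05). For each of these 6 lists the adjusted p = 0.0524 with an estimated correlation. Adjusted over the list alone the counts were 18 higher for hypoxia, 13 higher for immediate early genes and 2 lower for NRF2 targets (1 over all genes), and equal for the other 3 lists. Examples are Hspa5 at 1.39 ± 0.04, Hmox1 at 2.03 ± 0.07, Socs3 at 1.73 ± 0.04 and Cdkn1a at 1.61 ± 0.04. Shear and vasomotor genes had 4 of 9 higher (adjusted p = 0.088), MHC class II 4 of 6 (0.0585) and ribosomal protein genes 13 of 26 higher and 5 lower (0.0502), without a call, as for cell cycle (0.793), cholesterol synthesis (0.954) and oxidative phosphorylation (0.676).

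In all, 3049 genes were higher and 2837 lower of 12534 tested in endothelial cells, 781 and 277 of them by at least 2-fold. Of 22 lists 11 were higher and 4 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.0524. Profiles held 9336635 to 11439218 UMIs. Of the genes that rose, 752 (24.7%) had under 10% of the CPM of the class with the highest level. Over all genes tested in endothelial cells this share was 16.7%. The clock genes Dbp (-3.00 ± 0.05) and Per3 (-1.84 ± 0.06) fell and Arntl rose by 2.77 ± 0.14.

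Astrocytes were compared to ask how the main glial support cell responded. Gfap, the intermediate filament gene of reactive astrocytes (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), rose from 150 ± 45.6 to 1039 ± 74.8 CPM (SD, n = 3). The protease inhibitor gene Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329) rose from 5.50 ± 2.12 to 167 ± 22.0 CPM. Tnfrsf12a rose by 3.79 ± 0.20, Hmox1 by 3.47 ± 0.37 and Socs3, an inhibitor of cytokine signalling, by 2.54 ± 0.35. The glutamate receptor gene Gria2 fell from 1067 to 443 CPM. Astrocytes lay in 2 clusters, with 93.7% of sham and 80.5% of MCAO cells in the larger one. The smaller one, with 6.34% and 19.5%, had an astrocyte score of 0.405 and a microglia score of 0.264.

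Of the pan-reactive astrocyte list 10 of 12 members rose, 11 adjusted over the list alone (median 2.74, adjusted p = 3.73e-12; adjusted p = 0.0696 with an estimated correlation), with Osmr, a receptor gene for oncostatin M, at 3.2. Lcn2 rose by 3.72 ± 0.19 and stood at 5.3% of its neutrophil CPM, and Timp1 by 5.27 ± 0.30 at 4.2% of its fibroblast CPM. The A1 list had 10 of 11 higher (median 1.19, adjusted p = 3.61e-06; adjusted p = 0.119 with an estimated correlation). Among the A2 list 8 of 9 were higher, 9 adjusted over the list alone (median 4.09, or 3.69 with the genes at 0 in sham at their bound, adjusted p = 4.02e-11; adjusted p = 0.0696 with an estimated correlation). Ptx3 of that list rose from 3.55 ± 3.57 to 92.7 ± 16.2 CPM, its highest level among the tested classes, and Tgm1 was at least 20.4-fold higher than in sham, where it had 0 UMIs.

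Heat shock genes had 14 of 15 higher and 0 lower (median 1, adjusted p = 1.24e-10; adjusted p = 0.032 with an estimated correlation), with the chaperone gene Hspa8 going from 801 ± 17.2 to 1599 ± 41.5 CPM. Genes of p53 targets and cell death had 9 of 14 higher, 12 adjusted over the list alone (median 1.04, adjusted p = 4.03e-09; adjusted p = 0.0352 with an estimated correlation), with Cdkn1a at 3.68 ± 0.26. Cytokines and chemokines had 13 of 17 higher, 16 adjusted over the list alone (median 3.67, adjusted p = 4.43e-13; adjusted p = 0.032 with an estimated correlation). For 6 of them (Csf1, Cxcl16, Ccl12, Ccl3, Ccl4 and Tnf) astrocytes stood at a median over the genes of 9.49% to 10.1% of the level in microglia, where microglia markers stood at 9.72% to 12.6%, with Csf1 alone at 26.9% to 33.1% in MCAO and 118% to 190% in sham. The interferon list's call (6 higher, 1 lower of 19, median 0.39, adjusted p = 0.0481; adjusted p = 0.215 with an estimated correlation) was lost without members under 10% of the highest class (median 0.09).

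Immediate early genes had 15 of 18 higher (median 0.89, adjusted p = 1.71e-10; adjusted p = 0.143 with an estimated correlation), and extracellular matrix genes 13 of 15, with 1 lower adjusted over the list alone (1.33, and 1.33 with Thbs1 at its bound, 4.39e-10; adjusted p = 0.0731 with an estimated correlation). ER stress genes had 13 of 16 higher, 14 adjusted over the list alone (0.83, 1.34e-07; adjusted p = 0.0731 with an estimated correlation), with Hspa5 at 1.26 ± 0.08. Ribosomal protein genes had 25 of 26 higher, 26 adjusted over the list alone (0.54, 1.66e-11; adjusted p = 0.149 with an estimated correlation). NRF2 targets had 8 of 16 higher, 10 adjusted over the list alone (0.56, 5.54e-05; adjusted p = 0.17 with an estimated correlation), and NF-kB genes 5 of 10 (0.96, 0.000269; adjusted p = 0.143 with an estimated correlation). MHC class I had 7 of 13 higher, 8 adjusted over the list alone (0.48, 0.00136; adjusted p = 0.311 with an estimated correlation), and MHC class II 4 of 6, 5 adjusted over the list alone (0.76, 0.00315; adjusted p = 0.311 with an estimated correlation). Hypoxia and glycolysis had 9 of 23 higher and 2 lower, 10 higher adjusted over the list alone (0.22, 0.0163; adjusted p = 0.215 with an estimated correlation), and cell cycle genes had no call (0.436).

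Cholesterol synthesis genes fell, 9 of 18 lower and 0 higher, 11 adjusted over the list alone (median -0.44, adjusted p = 5.18e-05; adjusted p = 0.207 with an estimated correlation), with Mvd from 55.2 to 26.0 CPM. Oxidative phosphorylation had 8 of 29 lower and 0 higher, 9 adjusted over the list alone (median -0.13, adjusted p = 0.00521; adjusted p = 0.541 with an estimated correlation). Homeostatic astrocyte genes had 9 of 19 lower and 1 higher, or 2 higher adjusted over the list alone (median -0.18, adjusted p = 0.0469; adjusted p = 0.541 with an estimated correlation). The gap junction gene Gja1 fell by 0.47 ± 0.08 and the glutamate transporter gene Slc1a3 by 0.38 ± 0.07, while the water channel gene Aqp4 rose by 0.36 ± 0.08. These 3 are also naming markers.

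Over the 10360 genes tested in astrocytes, 1337 were higher and 1140 lower, 532 and 231 of them by at least 2-fold. Without the smaller cluster, an alternative chosen after seeing the data, 1623 genes changed and 702 were lower. Of 20 lists 16 were higher and 3 lower, and 3 calls held with an estimated correlation. No list was tested without the smaller cluster. Profiles held 901872 to 2577691 UMIs. Of the genes that rose, 250 (18.7%) were under 10% of the CPM of the class with the highest level. Over all genes tested in astrocytes this share was 8.2%. Markers of oligodendrocytes had 8 higher (median 0.82, adjusted p = 6.83e-05; adjusted p = 0.0696 with an estimated correlation) and ependymal markers 5 lower, 6 adjusted over the list alone (-1.68, 0.000202; adjusted p = 0.215 with an estimated correlation). Monocyte-derived cell markers had 4 of 7 higher (0.71, 0.00166; adjusted p = 0.262 with an estimated correlation) and neutrophil markers 2 of 6 (0.45, 0.0332; adjusted p = 0.381 with an estimated correlation). Microglia markers had 5 of 10 higher and 0 lower, without a call (0.34, 0.126), and stood in astrocytes at 2.56% to 3.36% of their level in microglia in sham and 9.72% to 12.6% in MCAO. The homeostatic list, which shares markers with this set, fell in microglia by a median of 1.78. Much of the rise in percent thus reflects a lower level in microglia. Erythrocyte markers had 3 of 4 higher, 4 adjusted over the list alone (3.16, 7.75e-05; adjusted p = 0.207 with an estimated correlation). With doublets kept Nnat (-1.63 ± 0.12) turned to 0.27 and Tmem119, a microglia marker (0.48 ± 0.14), to -0.44, as given in the closing section.

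**Figure D2:**
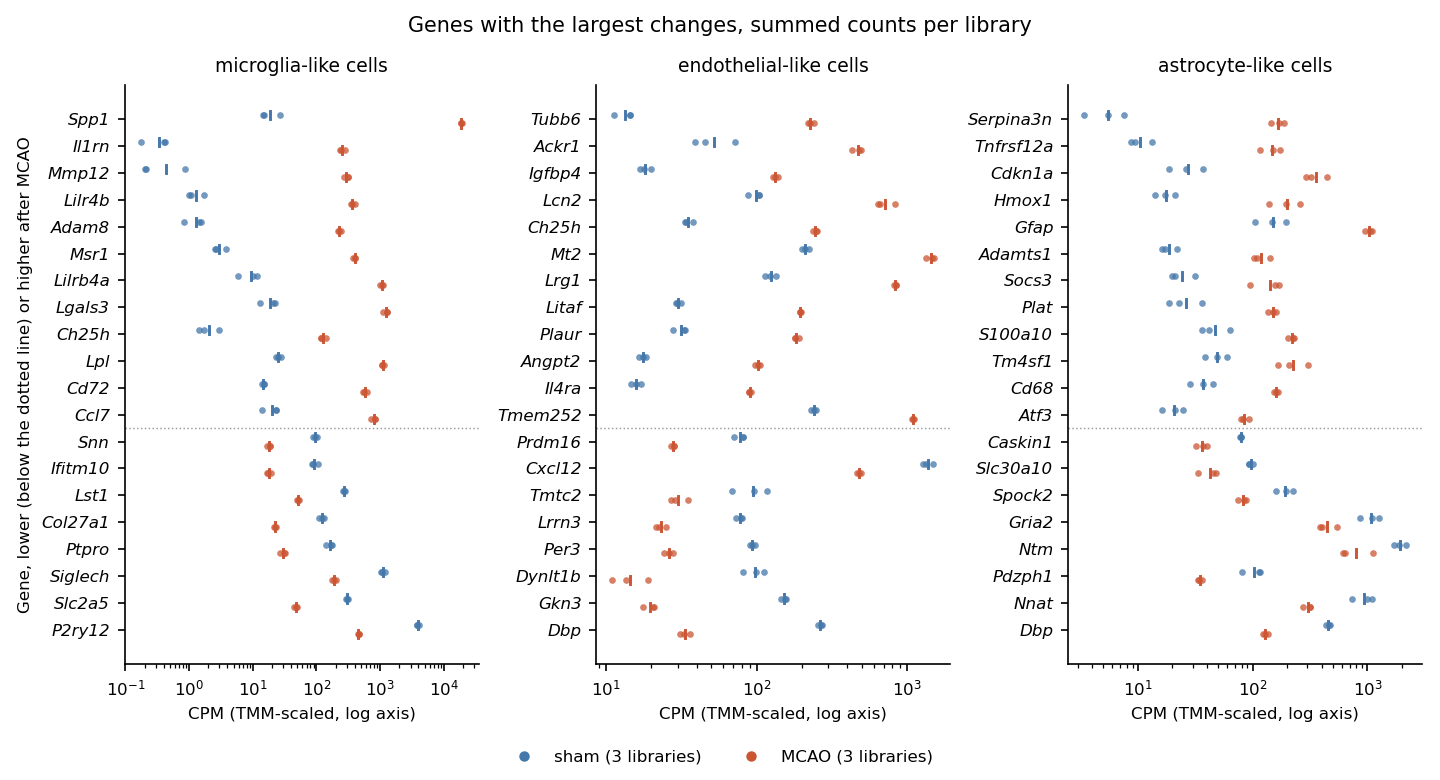
CPM in each library (log axis) of the 12 genes with the highest and the 8 with the lowest log2 change in microglia, endothelial cells and astrocytes, with a dot per library for 3 sham and 3 MCAO libraries. In microglia Spp1 lies at a mean of 18.6 CPM in sham and 18870 CPM in MCAO.

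The remaining 9 tested classes show how far the response extended beyond the main classes. In monocyte-derived cells the arginase gene Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) was at least 1180-fold higher, at 3798 ± 463 CPM against 0 UMIs in sham. All 22 cell cycle genes fell in this class (median -4.13, adjusted p = 2.28e-15; adjusted p = 0.19 with an estimated correlation), and hypoxia genes had 20 of 24 higher (median 1.22, adjusted p = 2.53e-08; adjusted p = 0.0754 with an estimated correlation). The cells came from different clusters, 1 with 78.6% of the MCAO and another with 98.6% of the sham cells. Border macrophages raised Spp1 from 21.7 to 6221 CPM, and Saa3, with 0 UMIs in sham, was at least 2178-fold higher. All 13 of their extracellular matrix genes rose (median 1.55, adjusted p = 1.5e-08; adjusted p = 0.0466 with an estimated correlation).

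Oligodendrocytes raised Serpina3n from 1.83 to 297 ± 50.6 CPM and Cdkn1a from 39.4 to 1154 CPM. All 10 disease-associated oligodendrocyte genes tested rose (median 2.05, adjusted p = 3.08e-10; adjusted p = 0.0768 with an estimated correlation). Myelin genes had 11 of 14 lower and 0 higher, or 1 higher adjusted over the list alone (median -0.48, adjusted p = 1.81e-05; adjusted p = 0.195 with an estimated correlation). In smooth muscle the endothelin receptor gene Ednrb rose by 5.99 ± 0.27, and 15 of 18 immediate early genes rose (median 0.53, adjusted p = 2.36e-08; adjusted p = 0.0369 with an estimated correlation). Choroid plexus epithelium raised the secreted glutathione peroxidase gene Gpx3 from 8.74 to 205 CPM, and 20 of 26 ribosomal protein genes fell, 22 adjusted over the list alone (median -0.25, adjusted p = 1.54e-07; adjusted p = 0.238 with an estimated correlation). Pericytes raised Il11, which had 1 UMI in sham, to 760 ± 184 CPM.

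Changed genes numbered 2236 in monocyte-derived cells, 2137 in border macrophages, 1864 in smooth muscle, 1639 in oligodendrocytes, 1265 in choroid plexus epithelium, 672 in pericytes, 518 in neutrophils, 166 in T or NK lymphocytes and 73 in fibroblasts. Without 1 library the count was as low as 37 and as high as 169 in fibroblasts (without MCAO 2 and sham 3), 67 in T or NK lymphocytes and 340 in neutrophils (both without MCAO 2). With profiles thinned to the smallest total it was 302 in monocyte-derived cells, 127 in pericytes, 256 in neutrophils, 72 in T or NK lymphocytes and 38 in fibroblasts. Of the genes that rose in choroid plexus epithelium 51.3% were under 10% of the CPM of the class with the highest level. Over all genes tested there this share was 17.5%. Genes that share reads with near-identical copies, such as Dynlt1b, Lilr4b and Lilrb4a, and Hspa1a and Hspa1b, are uncertain.

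**Figure D3:**
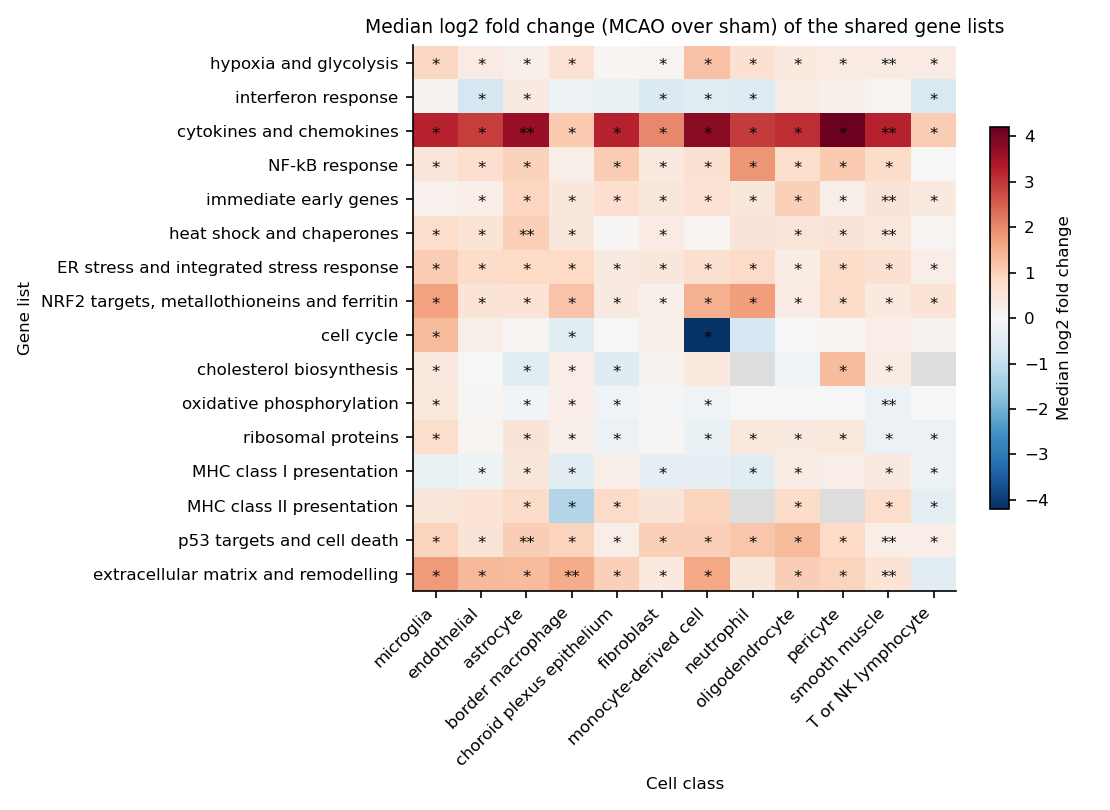
Median log2 change of 16 gene lists (vertical) in the 12 tested classes (horizontal), where * marks an adjusted p under 0.05 in camera, ** one that also holds with an estimated correlation, and grey a list with fewer than 3 members tested. The cell cycle list has its lowest median, -4.13, in monocyte-derived cells.

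The last comparison asks whether the change differed between the main classes. Igfbp4, which encodes an insulin-like growth factor binding protein, fell in microglia (-1.18) and rose in endothelial cells (2.87), a difference of 4 ± 0.13 (adjusted p = 9.93e-27). Rsad2, an antiviral gene, rose in microglia (2.27) and fell in endothelial cells (-0.92), a difference of -3.23 ± 0.19 (adjusted p = 1.45e-06). Slc7a11, the cystine transporter gene, rose in microglia (3.39) and fell in astrocytes (-0.34), a difference of -3.71 ± 0.16 (adjusted p = 2.59e-21). Mt2 rose more in endothelial cells (2.77) than in astrocytes (0.57), a difference of -2.18 ± 0.07 (adjusted p = 6.82e-67). The change differed in 5404 of 13145 genes between microglia and endothelial cells, 3623 of 12594 between microglia and astrocytes, and 1796 of 13459 between endothelial cells and astrocytes. DESeq2's size factors moved the balance of these: 45.6% of the first set were higher in endothelial cells against 54.7% with those factors, and 52.2% of the last set were higher in astrocytes against 41.8%.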

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

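The tests of microglial RNA, hemoglobin and the clock were chosen only after their patterns had been seen, with bounds written before each test's own value was seen, except that the look at single genes for microglial RNA had no bound, while the tests of differences between classes and the splits were planned. The change after MCAO differed between microglia and endothelial cells in 5404 genes, between microglia and astrocytes in 3623 and between endothelial cells and astrocytes in 1796, by a test of the difference itself. These are differences of log2 changes with adjusted p-values from edgeR.

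In endothelial cells the change was higher than in microglia for Igfbp4 (4 ± 0.13), Ifitm10 (3.12 ± 0.12), Ecscr (3.01 ± 0.05), Snn (2.86 ± 0.11) and Zeb1 (2.62 ± 0.13). It was lower for Dab2 (-4.12 ± 0.07), Rsad2 (-3.23 ± 0.19), Ch25h (-3.18 ± 0.18), Csf1 (-2.98 ± 0.11) and Lilr4b (-2.96 ± 0.51). In astrocytes it was higher than in microglia for Ifitm10 (5 ± 0.42), Parvg (4.33 ± 0.62), Rtn4rl1 (3.63 ± 0.59) and March1 (3.24 ± 0.56), and lower for Slc7a11 (-3.71 ± 0.16), Fabp5 (-3.57 ± 0.14), Lilr4b (-3.44 ± 1.15), Ptchd4 (-3.33 ± 0.86) and Sdc4 (-3.32 ± 0.11). Several of these rest on genes near the floor in one class: Ifitm10, Parvg, Rtn4rl1 and March1 stood at a mean of 6.67, 3.75, 2.73 and 4.12 CPM in astrocytes against 57.2, 66.7, 52.2 and 66.5 in microglia, and Ptchd4 at 0.465 CPM in microglia against 51.1 in astrocytes. Lilr4b stood at 9.31 CPM in endothelial cells and 12.6 in astrocytes against 175 in microglia. Parvg and Rtn4rl1 were not tested on their own in astrocytes, nor Ptchd4 in microglia. Against endothelial cells, astrocytes had higher changes of Osmr (2.56 ± 0.26), Tnfrsf12a (2.17 ± 0.22), Srgn (2.17 ± 0.13), Cdkn1a (2.06 ± 0.28) and Tm4sf1 (1.99 ± 0.40). Lower ones were those of Chst1 (-3.22 ± 0.16), G0s2 (-2.85 ± 0.22), Igfbp4 (-2.57 ± 0.36), Phactr3 (-2.42 ± 0.23) and Mt2 (-2.18 ± 0.07). Here too some stood low in one class: G0s2, Phactr3 and Chst1 at a mean of 5.50, 4.26 and 12.7 CPM in endothelial cells against 81.2, 111 and 185 in astrocytes, and Igfbp4 at 10.0 in astrocytes against 75.1 in endothelial cells.

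The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each result tested. The real split called 7234 genes in microglia, 5886 in endothelial cells, 2477 in astrocytes, 10570 in the other classes, 12 classes by abundance, and 5404, 3623 and 1796 differences, and the highest of the other splits called 0 in each. For gene lists in the main classes the real split called 49 and the highest other split 36. By class these were 15 and 13 in microglia, 15 and 14 in endothelial cells and 19 and 16 in astrocytes, a small excess in each. Every other split mixes sham and MCAO libraries on both sides. It thus keeps part of the MCAO difference and puts the rest into the spread within a side. Neither the 0 calls of genes nor the 36 of lists is a count free of that difference, so the splits cannot decide whether the calls came from the grouping.

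Cytokine and chemokine genes rose in endothelial cells and astrocytes as well as in microglia. In camera with an estimated correlation the call held only in astrocytes (adjusted p = 0.032, against 0.217 in endothelial cells and 0.105 in microglia). Astrocytes included a cluster with a microglia score of 0.264 beside an astrocyte score of 0.405, with 6.34% of sham and 19.5% of MCAO astrocytes. The list was not tested without that cluster, so microglia or mixed cells in it also stay open as a source. The endothelial call was also lost without members under 10% of the highest class. If microglial RNA in other cells' droplets were the source, members with their highest level in microglia would stand there at the ratio of the microglia markers. In endothelial cells the median member stood at 0.915 to 0.992 times that ratio in the 3 MCAO libraries (8 genes; 1.98 to 2.42 in sham), and in astrocytes at 0.807 to 1.03 times (6 genes; 1.26 to 1.72 in sham), within the limit of 2 times set beforehand for the MCAO libraries. The markers' ratio itself moved, from 2.12% to 2.84% in sham to 4.52% to 5.84% in MCAO in endothelial cells. In astrocytes it was 2.56% to 3.36% in sham and 9.72% to 12.6% in MCAO. The homeostatic list, which shares markers with this set, fell in microglia (median -1.78). A lower level in microglia raises the ratio, so meeting the limit cannot decide whether microglial RNA is the source. Csf1 stood apart, at 4.74 to 5.45 times that ratio in endothelial cells and 2.38 to 3.41 times in astrocytes, and in sham at 159% to 222% and 118% to 190% of its microglial level, which argues against microglial RNA as the main source of Csf1 RNA in either class and leaves its rise open. In endothelial cells Cxcl10 stood at 1.88 to 2.12 times the marker ratio and Cxcl16 at 1.44 to 1.94 times. In sham they stood at 7.69% to 69.25% and 8.44% to 11.2% of their microglial level, well above the markers, so their source stays open. For the remaining genes, at 0.494 to 1.17 times in endothelial cells and 0.699 to 1.12 times in astrocytes, microglial RNA may be the source. Expression of these genes by the cells themselves, at a level like the markers' share, stays open.

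Erythrocyte markers rose in microglia (median 4.22, adjusted p = 0.0271; adjusted p = 0.513 with an estimated correlation), endothelial cells (4.34, 0.000156; adjusted p = 0.217 with an estimated correlation) and astrocytes (3.16, 7.75e-05; adjusted p = 0.207 with an estimated correlation). Free hemoglobin RNA spread evenly over all droplets would give each class a like number of hemoglobin UMIs per cell, but the highest class had 8.08 to 9.95 times that of the lowest in the 3 MCAO libraries. The highest class differed between them: microglia in MCAO 1 (2.18 per cell, 1.78 and 0.625 in MCAO 2 and 3), T or NK lymphocytes in MCAO 2 (2.51 on 112 cells, 0.349 and 0.562 in MCAO 1 and 3) and endothelial cells in MCAO 3 (2.98, 1.45 and 1.53 in MCAO 1 and 2). The lowest class had 0.269, 0.281 and 0.299 in MCAO 1, 2 and 3. That argues against evenly spread RNA as the whole cause. Endothelial cells stayed high in each MCAO library, while microglia and T or NK lymphocytes did not. Erythrocytes attached to other cells, and uneven uptake of RNA, were not tested and stay open.

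Dbp, a clock output gene (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), fell in each of the 10 classes where it was tested. Under a different clock phase at sampling, Arntl, which cycles opposite to Dbp, would rise, and its median change was 2.41 over the 5 classes that tested it. It rose in smooth muscle (3.57 ± 0.41), endothelial cells (2.77 ± 0.14), choroid plexus epithelium (2.41 ± 0.51) and microglia (1.07 ± 0.28), and in astrocytes it did not pass (0.32 ± 0.26, adjusted p = 0.397), barely above the 0.3 set beforehand for each class. Sampling the groups at different times of day may account for this, and the labels give no time of collection. An effect of MCAO on the clock itself was not tested and stays open.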

How the results depend on the processing

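The splitting of mixed clusters, the adding of unnamed clusters and the leaving out of clusters with a marker score under 0.5 were chosen after seeing the data; the other alternatives were planned. Among the counts, 465 values stayed within 1.5 times the main count and 66 moved, and among the named genes 10005 kept direction and side of the threshold, 287 were weaker, 57 stronger and 11 reversed. For lists 2334 stayed the same, 249 were weaker and 59 stronger. Named differences kept 323 and 7 were weaker, and shares kept 223, with 4 weaker, 5 stronger and 3 reversed. After thinning to the smallest profile, 85.9% of the genes called in microglia were called in the same direction, which argues against depth as the source of most calls. In each alternative below the cause was not tested, except that a 2-fold minimum can only remove calls.

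DESeq2's test gave 1449 genes in astrocytes (849 higher, 600 lower), 1188 in border macrophages, 686 in choroid plexus epithelium, 950 in oligodendrocytes, 361 in pericytes, 1025 in smooth muscle, 95 in T or NK lymphocytes and 6625 over the other classes. Thinned profiles gave 1196 in astrocytes (712 and 484), 38 in fibroblasts, 302 in monocyte-derived cells, 256 in neutrophils, 127 in pericytes, 72 in T or NK lymphocytes and 6365 over the other classes. A 2-fold minimum gave 763 in astrocytes (532 and 231), 642 in border macrophages, 374 in choroid plexus epithelium, 1058 in endothelial cells (781 and 277), 2128 in microglia (1058 and 1070), 1296 in monocyte-derived cells, 470 in oligodendrocytes, 294 in pericytes, 473 in smooth muscle, 87 in T or NK lymphocytes and 4075 over the other classes.

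At most 5% mitochondrial UMIs gave 730 lower genes in astrocytes, 766 genes in choroid plexus epithelium, 868 in oligodendrocytes and 703 in smooth muscle. With no filter on counts there were 213 in fibroblasts and 265 in T or NK lymphocytes, with limma-voom 35 in fibroblasts, and with doublets kept 158 in fibroblasts and 822 in neutrophils. Without the low-score astrocyte clusters 1623 genes changed, 702 of them lower. With an estimated correlation 3 lists were called in the main classes, 0 and 0 in microglia, 0 and 0 in endothelial cells and 3 higher and 0 lower in astrocytes, and with fry 2 lists were lower in microglia. Over all classes and lists, marker lists included, fry left 216 results the same, with 23 stronger and 6 weaker. An estimated correlation left 85 the same and made 160 weaker.

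Leaving out each library in turn gave 6713 to 7178 genes in microglia (3337 to 3506 higher, 3364 to 3698 lower), 5115 to 5861 in endothelial cells (2685 to 3017, 2406 to 2844) and 1925 to 2244 in astrocytes (1086 to 1248, 839 to 996). Other classes gave 8354 to 9794 together: 1707 to 1988 in border macrophages, 944 to 1416 in choroid plexus epithelium, 37 to 169 in fibroblasts, 1584 to 2061 in monocyte-derived cells, 340 to 507 in neutrophils, 1348 to 1589 in oligodendrocytes, 500 to 629 in pericytes, 1526 to 1850 in smooth muscle and 67 to 140 in T or NK lymphocytes. Fibroblasts had 39 genes without sham 1, 169 without sham 3, 45 without MCAO 1, 37 without MCAO 2 and 47 without MCAO 3. T or NK lymphocytes had 91 without sham 3, 86 without MCAO 1, 67 without MCAO 2 and 107 without MCAO 3, and neutrophils 340 without MCAO 2. Lists called numbered 47 to 50 (endothelial higher 11 to 13, astrocyte higher 15 to 16, astrocyte lower 1 to 3, with 1 without MCAO 3), classes by abundance 11 to 13, and differences 4723 to 5327, 2979 to 3391 and 1228 to 1601.

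With the replicate number as a replicate block, counts were 7146 in microglia, 5559 in endothelial cells, 2576 in astrocytes, 9876 over the other classes, 48 lists and 12 classes by abundance. Same-number libraries were not more alike than others (correlations of -0.132 to 0.059, against -0.124 to 0.129 for different numbers). With 3 libraries per group, taken as deviations from the group mean, this cannot exclude a shared day or batch.

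Direction turned for Nnat in astrocytes, from -1.63 to 0.0463 with 20% mitochondrial UMIs, 0.27 with doublets kept, 0.25 at resolution 0.5 and 0.30 without low-score clusters. Tmem119 in astrocytes turned to -0.44 with doublets kept, -0.43 at resolution 0.5, -0.43 at resolution 2.0, -0.44 with mixed clusters split and -0.49 without low-score clusters. In microglia H2-Ab1 turned to -0.57 with clusters split and Folr2 to -0.23 without low-score clusters. With TMM over classes the shares turned to -0.46 for border macrophages, -0.48 for fibroblasts and -0.35 for smooth muscle, and those of oligodendrocytes and choroid plexus epithelium no longer passed while that of ependymal cells did.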

Other observations

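No test was added for these values, which come from comparisons that were planned. In neutrophils, NF-kB genes had 6 of 8 higher and 0 lower (median 1.84, adjusted p = 0.000247; adjusted p = 0.105 with an estimated correlation). Their interferon response genes fell, with 5 of 16 lower and 0 higher, or 8 lower and 1 higher adjusted over the list alone (median -0.53, adjusted p = 0.00321; adjusted p = 0.315 with an estimated correlation). The same list was lower in monocyte-derived cells (10 of 20 lower, median -0.44, adjusted p = 0.00182; adjusted p = 0.403 with an estimated correlation), T or NK lymphocytes (3 of 12 lower, 4 adjusted over the list alone, -0.63, 0.000515; adjusted p = 0.271 with an estimated correlation) and fibroblasts (3 of 13 lower, 6 adjusted over the list alone, -0.60, 9.71e-06; adjusted p = 0.106 with an estimated correlation). The monocyte-derived cells of the groups came mostly from different clusters, one with 78.6% of the MCAO and another with 98.6% of the sham cells. Their lower values may thus be a difference between kinds of cells.

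Pericytes raised extracellular matrix genes (10 of 16 higher, median 0.95, and 0.95 with Tnc and Timp1 at their bound, adjusted p = 3.04e-08; adjusted p = 0.0564 with an estimated correlation). Their cholesterol synthesis genes had 7 of 11 higher, 8 adjusted over the list alone (median 1.33, adjusted p = 8.01e-06; adjusted p = 0.0858 with an estimated correlation), against 9 of 18 lower in astrocytes and 6 of 18 lower in choroid plexus epithelium, and the difference between these classes was not tested. In border macrophages MHC class II genes had 2 of 6 lower (median -1.22, adjusted p = 0.00149; adjusted p = 0.22 with an estimated correlation). In smooth muscle 20 of 29 oxidative phosphorylation genes fell, 22 adjusted over the list alone (median -0.24, adjusted p = 1.99e-05; adjusted p = 0.0369 with an estimated correlation). T or NK lymphocytes raised Socs3 by 2.38 ± 0.45 (adjusted p = 0.00534).

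Median, mean and test differed in sign for some lists without a call. These were interferon response in choroid plexus epithelium (median -0.28, mean 0.15), cholesterol synthesis in fibroblasts (0.16, -0.11), extracellular matrix in T or NK lymphocytes (-0.49, 0.18), cell cycle in oligodendrocytes (0.02, 0.03, test lower), oxidative phosphorylation in pericytes (-0.01, 0.01), ependymal markers in endothelial cells (-0.07, -0.04, test higher) and dendritic cell markers in microglia (0.13, 0.01, test lower).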
